A study of Bos taurus with 15 samples.

How the data were processed

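Endometrium, the lining of the uterus, was biopsied from 15 beef heifers (Bos taurus) on day 14 of pregnancy. The labels put 5 heifers in each of 3 fertility classes, High-fertile, Sub-fertile and Infertile. Per the labels' protocols, estrus was synchronised with hormones, an embryo produced in vivo was transferred on day 7 to the horn beside the corpus luteum, and the tissue was taken with forceps after the uterus had been flushed. How the classes were assigned, and what the flush recovered from each heifer, is not given in the sources used here. RNA was purified on RNeasy columns and sequenced from stranded TruSeq mRNA libraries, per the labels' protocols. Each library came from 1 heifer, so the spread within a class is between animals.

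The deposited table gives, for each heifer, a read count per gene and an FPKM value (fragments scaled by gene length and library size). FastQC, Subread, featureCounts and edgeR and the UMD3.1 genome build are named in the submitters' processing notes, and their versions, the strand setting and the treatment of reads with several possible origins are not given in the sources used here. The deposited counts are whole numbers that sum to 38017136 to 62858724 per library, and they were the values tested. The deposited FPKM values were used only to check the table, where their scale lay within 0.4% of the library totals, and to recover gene lengths. The table holds 32671 gene entries, of which 4555 are at 0 in every library. The gene names of 27 entries read as calendar dates, as a spreadsheet program leaves them, and these were not renamed. Gene symbols are those of the table, of which 20070 matched a current symbol in an annotation of another assembly, used for names alone, so no coordinates are given. Genes with near-identical copies, among them the immunoglobulin, BOLA (bovine major histocompatibility) and OAS1 genes, are uncertain, since reads could have been split between copies.

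Counts were analysed in R 4.3.3 with edgeR 4.0.16. Entries were kept with filterByExpr by class, which left 19962 genes, and libraries were scaled with TMM factors. One quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) held a mean for each class over all 15 libraries, with 12 residual degrees of freedom, and gave the 3 pairwise comparisons and a test of any difference among the classes. P values were two-sided and were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Every gene-level p printed is from this edgeR test unless another tool is named. Log2 fold changes are given with their standard errors and levels as CPM, counts scaled to library size and TMM factor, with the SD over 5 heifers. A count of 0 in a library allows a level of up to 3 counts, or 0.0477 to 0.0789 CPM by library, which covers counting error only.

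Lists of genes for 30 pathways and cell types were fixed with the tests, the alternatives and the rule for naming genes before the data were examined. The 28 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over 84 tests of lists. The lists of mitochondrially encoded genes (0 members in the table) and trophoblast genes (4 tested) had too few members. Beside it stand camera with the correlation estimated per list, fry, and an exact two-sided permutation test of the mean log2 CPM of each list over the 252 ways to assign 5 of 10 libraries, whose smallest p is 0.00794. Genes were named by rule: the 20 genes with a symbol and the smallest p in each comparison, since none passed the threshold, the 2 members of each list with the smallest p, and a fixed set of receptor, interferon, gland and marker genes. In each comparison a part of these is given as counts. Immunoglobulin genes named by a LOC number lie outside the rule and were chosen after their values were seen.

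The labels give no sequencing batch. The 372 tested genes described as pseudogenes or ribosomal RNA, whose counts depend on how reads with several origins are placed, split the libraries by average-linkage clustering into sets of 8, 5 and 2, without use of the class and after the data had been seen. The model was fitted again with these technical sets as a covariate, with 10 residual degrees of freedom, and values within the 8-library set were computed.

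Alternatives fixed in advance were other scalings (RLE, upper quartile, library size alone), no filter and a stricter one, DESeq2 1.42.0, limma-voom with sample quality weights, the edgeR likelihood ratio test, the quasi-likelihood test without robust estimation, only the 10 libraries compared, 1 surrogate variable (sva 3.50.0), a threshold of 0.10 and each library left out in turn. The correlation of fold changes that share the High-fertile libraries and the genes shared by both comparisons were set beside 40 simulations with no effect. The simulated and relabelled numbers of shared genes were added after the data had been seen. The test was tried on counts simulated from the real means, library sizes and dispersions with known changes. For Sub-fertile against High-fertile (19771 genes) it recovered 43.3% of 2-fold, 82.1% of 4-fold and 95.5% of 8-fold changes. For Infertile against High-fertile (19773 genes) the shares were 31.3%, 83.6% and 95.5%, and for Infertile against Sub-fertile (19799 genes) 47.8%, 86.6% and 98.5%. Of its calls, 5 of 152, 5 of 145 and 12 of 167 were on unchanged genes. The changed genes were drawn from those with higher mean counts, and the simulation left out the technical sets. The recovered shares therefore do not extend to genes with few counts. Python 3.11.15 was used for tables and plots.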

Results

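Transcript abundance was measured in endometrial biopsies from 15 heifers, 5 in each fertility class, on day 14 of pregnancy, when the bovine embryo elongates and begins to secrete interferon tau. The comparisons ask whether the endometrium of heifers of lower fertility differs from that of High-fertile heifers at this stage. Total counts were 40542008 to 56164970 in the High-fertile, 38017136 to 62858724 in the Sub-fertile and 40061511 to 51009815 in the Infertile libraries. COL3A1, a fibrillar collagen of connective tissue, took up to 1.88% of a library. Rank correlations between libraries were high, with medians from 0.955 to 0.975 for 14 libraries and 0.924 for Infertile replicate 2. The first principal component, with 26.6% of the variance, set Infertile replicate 2 (-120) and High-fertile replicate 1 (-70.0) apart from the other 13 libraries (-26.3 to 74.2).

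The libraries fell into 3 sets by the counts of pseudogenes and ribosomal RNA. They are called technical because of the genes that define them. That origin is inferred, since the labels name no batch, and a difference between heifers was not excluded. High-fertile replicate 1 and Infertile replicate 2 formed a set of 2, in which pseudogenes took 1.09% and 1.21% of counts, against 2.39% to 3.27% elsewhere. RN18S1 (18S ribosomal RNA) had no count in them. Sub-fertile replicates 1, 2 and 5 and Infertile replicates 3 and 5 formed a set of 5, in which LOC100295881 was at 42.3 to 53.8 CPM against 0.443 to 1.53 CPM in all others. The set of 8 held 4 High-fertile, 2 Sub-fertile and 2 Infertile libraries. No High-fertile library was in the 5-library set, so class and set were partly confounded. With class in the edgeR model, 6126 genes passed the threshold between the 5- and 8-library sets (2614 higher and 3512 lower in the 5-library set).

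Immunoglobulin and B cell transcripts were at lower values in Sub-fertile than in High-fertile endometrium, as a list called with the preset correlation and not with an estimated one. IGLL1-2, an immunoglobulin lambda-like gene by its symbol, was at 15.4 ± 3.93 CPM (SD, n = 5) in Sub-fertile and 199 ± 131 CPM (n = 5) in High-fertile heifers, a log2 fold change of -3.70 ± 0.625 (SE; edgeR adjusted p = 0.195). POU2AF1, a B cell transcriptional coactivator, was at 0.119 ± 0.0653 against 1.21 ± 0.897 CPM (log2 fold change -3.33 ± 0.619; edgeR adjusted p = 0.320). For both genes every Sub-fertile library lay below every High-fertile library. IGJ, the joining chain of secreted IgM and IgA, was at 12.2 ± 4.66 against 122 ± 88.8 CPM, with a log2 fold change of -3.32 and overlapping ranges. CD79A and CD79B, the signalling chains of the B cell receptor, had log2 fold changes of -3.24 and -3.90, at levels of 0.203 and 0.118 CPM in Sub-fertile libraries. High-fertile replicate 1, at 7.07 and 7.52 CPM, set the size of both differences, and without it they were -1.69 and -1.56. The same library held the least IGLL1-2 (46.0 CPM) and IGJ (15.3 CPM) of its class. The B cell receptor genes and these immunoglobulin genes were therefore not highest in the same heifer. None of these genes passed the threshold over all genes.

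The B and plasma cell list had 15 of 16 members lower. Of these, 9 were past the threshold adjusted over the list alone and 0 over all genes in the edgeR test, where 10 members were at an unadjusted p under 0.05. Its mean log2 CPM was -0.110 ± 0.263 in Sub-fertile and 1.14 ± 0.670 in High-fertile libraries (n = 5 each; camera adjusted p = 9.14e-05). The adjusted p was 0.481 with an estimated correlation (unadjusted p = 0.0203). The exact permutation p was 0.00794, the smallest this design allows, and 0.222 adjusted. Within the 8-library set the list differed by -1.21. Its 2 Sub-fertile libraries were at -0.471 and -0.253 and its 4 High-fertile libraries from 0.631 to 1.02. The median log2 fold change of the members was -1.94, and -1.41 with the set as a covariate. It was -0.73 without High-fertile replicate 1 and down to -2.43 with another library left out, and the call held each time. All 10 immunoglobulin genes examined, chosen after their values were seen, were lower, with a median log2 fold change of -3.66, or -3.95 with the set as a covariate. LOC100847119, described as a lambda chain constant region, was at 1.01 ± 0.618 against 70.8 ± 59.6 CPM (log2 fold change -6.13 ± 0.899; edgeR adjusted p = 0.121). LOC524810, described as IgM, was at 4.42 ± 2.04 against 213 ± 167 CPM.

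**Figure D1:**
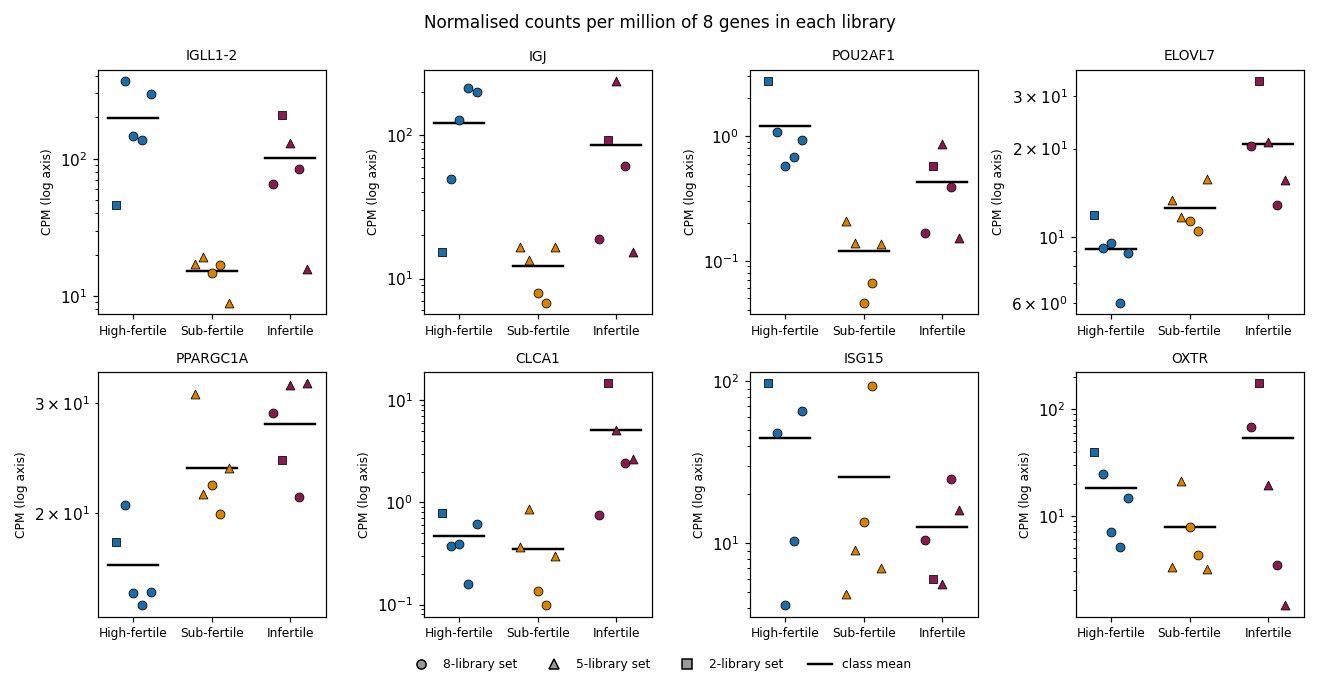
Normalised CPM (vertical log axis) of 8 genes in each of the 15 libraries by fertility class. Symbols mark the technical library set, colours the class, and bars the arithmetic class mean. All 5 Sub-fertile libraries lay between 8.95 and 19.3 CPM for IGLL1-2, and the High-fertile libraries between 46.0 and 370 CPM.

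Complement, macrophage, vascular and matrix genes were mostly at lower values in Sub-fertile endometrium, as lists called with the preset correlation alone. CFD (complement factor D) was at 9.96 ± 3.45 against 17.2 ± 3.32 CPM and C3 at 61.6 ± 17.9 against 104 ± 31.3 CPM. In the complement list 18 of 22 members were lower (camera adjusted p = 0.00164; adjusted p = 0.481 with an estimated correlation). CSF1R, the receptor of a macrophage growth factor, had a log2 fold change of -0.66 ± 0.227 and C1QB -0.81 ± 0.303. In the macrophage and dendritic cell list 17 of 19 members were lower, with a camera adjusted p of 0.00170 and an adjusted p of 0.900 with an estimated correlation. The endothelium list had 19 of 20 members lower, with ENG at -0.66 and ESAM at -0.67, or -0.42 without High-fertile replicate 5 (camera adjusted p = 0.00314; adjusted p = 0.900 with an estimated correlation). Extracellular matrix remodelling had 24 of 29 members lower, with a camera adjusted p of 0.00593 and an adjusted p of 0.917 with an estimated correlation. Among them were TIMP1, an inhibitor of matrix metalloproteinases (log2 fold change -0.58), and MMP23B (-0.64). Hypoxia and glycolysis had 20 of 27 members lower (camera adjusted p = 0.0435; adjusted p = 0.900 with an estimated correlation). PFKP was at -0.58 and LDHA, which makes lactate, the other way at 0.77. Smooth muscle, with 15 of 15 members lower and a median of -0.84, was not called (camera adjusted p = 0.0760; adjusted p = 0.917 with an estimated correlation), nor were stromal fibroblasts, with 16 of 20 lower and a median of -0.18 (camera adjusted p = 0.101; adjusted p = 0.917 with an estimated correlation). In none of the 5 called lists did a member pass the threshold adjusted over the list alone in the edgeR test, where 8, 6, 3, 1 and 4 members were at an unadjusted p under 0.05. The calls of the endothelium, matrix and hypoxia lists ended with the technical set as a covariate, with median log2 fold changes of -0.15, -0.11 and -0.03 against -0.45, -0.40 and -0.28. With 1 library left out the endothelium median lay between -0.55 and -0.29 and the matrix median between -0.45 and -0.23. The matrix call also ended without High-fertile replicate 5 or Sub-fertile replicate 3. The hypoxia call also ended without High-fertile replicate 1, Sub-fertile replicate 1 or Sub-fertile replicate 2. The complement call ended within the 8-library set (median -0.36).

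Among the 20 named genes with the smallest p, 15 were lower and 5 higher in Sub-fertile heifers, with edgeR adjusted p from 0.195 to 0.360. Of these, 16 had classes that did not overlap, which their choice by smallest p favours. Over all genes tested 1012, or 5.07%, did not overlap, where chance gives 0.794%. CORO1A, an actin-binding protein of leukocytes, was at 7.02 ± 1.54 against 14.0 ± 4.63 CPM, TNFAIP8L2, a regulator of immune responses, at 1.003 ± 0.1251 against 1.97 ± 0.241 CPM. ACE, the angiotensin-converting enzyme, was at 19.1 ± 3.13 against 37.0 ± 11.5 CPM. DEAF1, a transcription factor, had a log2 fold change of -0.85 ± 0.203 and DOC2A, a calcium sensor of exocytosis, -1.14 ± 0.251. On the higher side AZIN1, an inhibitor of antizyme that favours polyamine synthesis, was at 249 ± 8.58 against 186 ± 20.2 CPM (log2 fold change 0.42 ± 0.115), DPY19L4 at 126 ± 20.9 against 74.6 ± 14.1 CPM and SLC9A7, a sodium-proton exchanger, at 42.8 ± 6.80 against 28.8 ± 5.37 CPM. SRD5A2, a steroid 5-alpha-reductase, had 45 counts over the Sub-fertile and 4 over the High-fertile libraries.

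Progesterone and oxytocin receptor genes did not differ beyond the spread between heifers. PGR was at 5.95 ± 4.81 in Sub-fertile and 10.1 ± 3.05 CPM in High-fertile heifers (log2 fold change -0.76 ± 0.737; 0.50 with the technical set as a covariate), and OXTR at 7.90 ± 7.57 against 18.2 ± 14.2 CPM (-1.20 ± 1.01). Leaving out 1 library moved OXTR between -0.70 and -1.97, and PGR to -1.36 without Sub-fertile replicate 3. MX2, an antiviral gene induced by interferon, was at 14.9 ± 15.2 against 29.9 ± 33.3 CPM, with a log2 fold change of -0.08 without High-fertile replicate 1 and -1.88 without Sub-fertile replicate 4. Of the progesterone-responsive and conceptus-elongation genes 26 of 33 were lower (camera adjusted p = 0.105), with CST3, a secreted cystatin, at 86.2 ± 11.5 against 127 ± 21.0 CPM. This list passed with the technical set as a covariate (camera adjusted p = 0.0431, and unadjusted p = 0.160 with an estimated correlation). Within the 8-library set its mean log2 CPM differed the other way, by 0.059, with overlapping ranges. HSPA1A, a heat shock gene, was at 225 ± 42.7 against 382 ± 110 CPM, and the list of immediate early and heat shock genes did not pass (adjusted p = 0.158). The T and NK cell list, with 18 of 26 members lower, also missed the threshold (camera adjusted p = 0.114), CD5 at 1.41 ± 0.117 against 2.36 ± 0.399 CPM. With the technical set as a covariate it passed, at a median log2 fold change of -0.22 (camera adjusted p = 0.000631, and unadjusted p = 0.176 with an estimated correlation). Within the 8-library set the 2 Sub-fertile libraries had list means of 0.544 and 1.62, below and above all High-fertile ones (1.17 to 1.54). SLC38A3, a glutamine transporter, had a log2 fold change of -1.36 ± 0.396 while its list of amino acid transporters had 15 of 30 members lower (camera adjusted p = 0.941).

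Over all genes, 0 of 19962 passed the threshold for Sub-fertile against High-fertile in the edgeR quasi-likelihood test (smallest adjusted p = 0.121), with 2738 at an unadjusted p under 0.05 (1313 higher, 1425 lower) where chance gives 998. The edgeR likelihood ratio test passed 44 genes, DESeq2 19, limma-voom 0 without sample weights and 7162 with sample quality weights. With the technical set as a covariate 501 genes were at an unadjusted p under 0.05, limma-voom with quality weights passed 0, and within the 8-library set 1528 were at an unadjusted p under 0.05. Of the 2738 genes, 1776 (64.9%) also passed between the 5- and 8-library sets, 1775 of them in the same direction, against 30.7% of all genes.

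**Figure D2:**
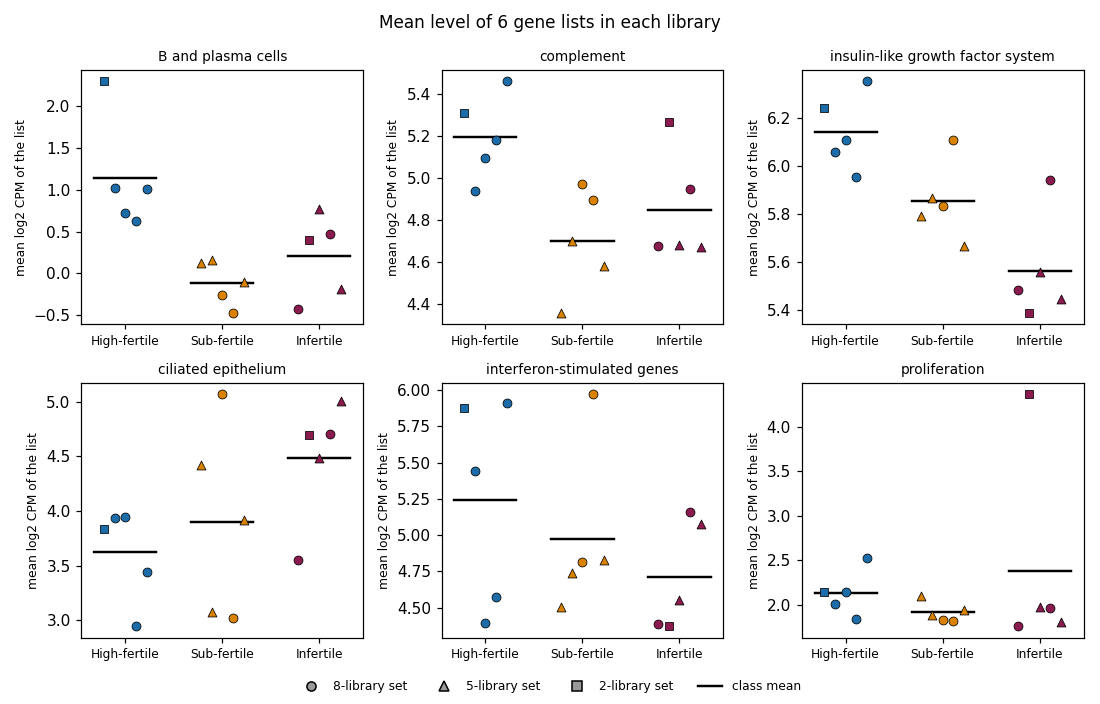
Mean log2 CPM (vertical axis) of 6 gene lists in each of the 15 libraries by fertility class. Symbols mark the technical library set, colours the class, and bars the class mean. For the B and plasma cell list all 5 Sub-fertile libraries (-0.471 to 0.160) lay below the High-fertile libraries (0.631 to 2.30), and for proliferation Infertile replicate 2 (4.37) stood above the other 14 libraries.

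Ciliated cell genes were mostly at higher values, and insulin-like growth factor, complement and interferon-stimulated genes at lower values, in Infertile than in High-fertile endometrium, as lists called with the preset correlation. All 19 measured members of the ciliated epithelium list were higher, with ARMC3 at 40.5 ± 20.6 against 14.3 ± 4.72 CPM and SNTN (sentan, of the ciliary tip) at 2.29 ± 1.29 against 0.749 ± 0.389 CPM (n = 5 each; camera adjusted p = 1.46e-07; adjusted p = 0.900 with an estimated correlation). In the insulin-like growth factor list 12 of 16 members were lower, among them IGFBP2, a binding protein of these factors, at 14.2 ± 9.08 against 69.1 ± 52.7 CPM and INSR, the insulin receptor, at 147 ± 23.1 against 177 ± 8.40 CPM. The log2 fold change of INSR was -0.27, and -0.17 without Infertile replicate 2. The mean log2 CPM of this list was 5.56 ± 0.220 in Infertile and 6.14 ± 0.156 in High-fertile libraries, without overlap (camera adjusted p = 0.00311; adjusted p = 0.226 with an estimated correlation; exact permutation p = 0.00794, 0.222 adjusted). It was the 1 list whose members moved together in fry at an adjusted p under 0.05 (adjusted p = 0.0258). Complement had 15 of 22 members lower, 4 past the threshold adjusted over the list alone, with a camera adjusted p of 0.00358 and an adjusted p of 0.481 with an estimated correlation. Its median log2 fold change was -0.34, and between -0.66 and -0.20 with 1 library left out. C4A was at 45.7 ± 27.3 against 125 ± 27.9 CPM and SERPING1, an inhibitor of the classical pathway, at 146 ± 54.0 against 260 ± 52.9 CPM.

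Of the interferon-stimulated genes 36 of 37 were lower in Infertile heifers, with a median log2 fold change of -0.58 (camera adjusted p = 6.02e-05; adjusted p = 0.917 with an estimated correlation). ISG15, a ubiquitin-like protein induced by interferon, was at 12.6 ± 8.01 against 44.9 ± 38.7 CPM. MX1 was at 165 ± 78.4 against 291 ± 170 CPM, MX2 at 11.5 ± 5.49 against 29.9 ± 33.3 CPM. IRF9 was at 39.8 ± 12.8 against 69.1 ± 22.1 CPM and ZBP1 at 5.11 ± 2.16 against 13.9 ± 9.04 CPM. The log2 fold change of MX2 was -1.37, and -0.46 without High-fertile replicate 1. The ranges of the list mean overlapped (4.37 to 5.16 against 4.40 to 5.91; exact permutation p = 0.143), and the call ended without the 2-library set (median -0.35). The B and plasma cell list had 15 of 16 members lower, 8 past the threshold adjusted over the list alone (camera adjusted p = 0.000493; adjusted p = 0.481 with an estimated correlation). CD79A was at 0.374 ± 0.146 against 1.94 ± 2.87 CPM and MS4A1, the B cell antigen CD20, at 0.499 ± 0.429 against 4.65 ± 9.11 CPM. High-fertile replicate 1 was the highest of its class on this list (2.30 against 0.631 to 1.02) and carried these genes. It held 20.9 CPM of MS4A1 against 0.517 to 0.643 CPM in the other 4, and without it the log2 fold change of MS4A1 went from -3.21 to -0.20 and that of CD79A from -2.36 to -0.80. LOC100847119, chosen after its values were seen, had a log2 fold change of -2.72 ± 0.757, and the 10 immunoglobulin genes a median of -1.01. Endothelium had 18 of 20 members lower (TIE1 -0.56, CDH5 -0.47, or -0.27 without High-fertile replicate 5; camera adjusted p = 0.00164; adjusted p = 0.900 with an estimated correlation), a call that ended within the 8-library set (median -0.18). Its median was -0.33, and between -0.45 and -0.19 with 1 library left out. Matrix remodelling had 19 of 29 lower (TIMP1 -0.53, PLAT -0.57; camera adjusted p = 0.00395; adjusted p = 0.917 with an estimated correlation), a call that ended without High-fertile replicate 5 or Infertile replicate 5, where the median went from -0.22 to -0.02 and -0.05.

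The 20 genes with the smallest p in this comparison, 14 higher and 6 lower in Infertile heifers, each had an edgeR adjusted p of 0.435. Of these, 16 had classes that did not overlap, which their choice by smallest p favours. Over all genes tested 444, or 2.22%, did not overlap, where chance gives 0.794%. ELOVL7, a fatty acid elongase, was at 20.8 ± 8.09 against 9.11 ± 2.10 CPM (log2 fold change 1.19 ± 0.246), and PPARGC1A, a coactivator of mitochondrial biogenesis, at 27.7 ± 4.87 against 16.5 ± 2.69 CPM (0.75 ± 0.164). APOO, a protein of mitochondrial cristae, was at 10.99 ± 1.70 against 6.88 ± 0.704 CPM. AZIN1 was at 266 ± 39.5 against 186 ± 20.2 CPM, and HNMT, which breaks down histamine, at 28.8 ± 8.73 against 14.9 ± 1.44 CPM. Lower in Infertile heifers were NOTCH4, a Notch receptor of endothelium, at 27.1 ± 8.52 against 56.2 ± 15.7 CPM (log2 fold change -1.05 ± 0.231), and ATP10A, a lipid flippase, at 18.7 ± 3.77 against 38.3 ± 7.42 CPM. ZHX3, a transcriptional repressor, was at 72.5 ± 10.3 against 107 ± 12.6 CPM, and RAMP3, a partner of the adrenomedullin receptor, at 27.3 ± 4.96 against 48.4 ± 11.9 CPM. CLCA1, a secreted protein of mucous epithelium, was at 5.13 ± 5.54 against 0.466 ± 0.242 CPM (log2 fold change 3.46 ± 0.768, or 2.56 without Infertile replicate 2). LYZ2, a lysozyme, was at 3.88 ± 2.996 against 0.928 ± 0.320 CPM, and FAM183A at 11.7 ± 5.26 against 3.44 ± 1.35 CPM.

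OXTR and SERPINA14 had overlapping ranges in Infertile and High-fertile heifers. OXTR was at 53.7 ± 73.3 against 18.2 ± 14.2 CPM (log2 fold change 1.56, or 0.35 without Infertile replicate 2; edgeR adjusted p = 0.535). SERPINA14, a secreted serpin of the uterine glands, was at 5.99 ± 5.82 against 17.1 ± 15.3 CPM (log2 fold change -1.51, or -0.80 without High-fertile replicate 4). Of the progesterone-responsive and conceptus-elongation genes 22 of 33 were lower (camera adjusted p = 0.0514), a list that passed with the technical set as a covariate (camera adjusted p = 0.0402; p = 0.149 with an estimated correlation). TGM2, a transglutaminase, was at 658 ± 196 against 1039 ± 123 CPM without overlap, and APOA1 at 42.1 ± 12.1 against 80.7 ± 27.5 CPM. Over all genes 0 passed the threshold in the edgeR quasi-likelihood test (smallest adjusted p = 0.435), with 2201 at an unadjusted p under 0.05 (1425 higher, 776 lower) where chance gives 998, and 1529 with the technical set as a covariate. The edgeR likelihood ratio test passed 57, DESeq2 34, limma-voom with quality weights 0 and without weights 1. The unadjusted count was 1287 without Infertile replicate 5 and 3346 without Infertile replicate 1.

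Between Infertile and Sub-fertile endometrium no single gene passed the threshold in the edgeR quasi-likelihood test, and small p values and separate ranges were fewer than chance gives. Mean values of the immunoglobulin genes examined were higher in Infertile heifers. IGLL1-2 was at 101 ± 72.4 in Infertile and 15.4 ± 3.93 CPM in Sub-fertile heifers (n = 5 each; log2 fold change 2.71 ± 0.599; edgeR adjusted p = 0.998). IGJ was at 85.9 ± 92.4 against 12.2 ± 4.66 CPM and POU2AF1 at 0.429 ± 0.297 against 0.119 ± 0.0653 CPM. All 10 immunoglobulin genes, chosen after their values were seen and not tested as a list, were higher, with a median log2 fold change of 2.56. The fixed B and plasma cell list was not called, with 10 of 16 members higher (camera adjusted p = 0.158), 1 past the threshold adjusted over the list alone. CLCA1 was at 5.13 ± 5.54 against 0.351 ± 0.304 CPM (log2 fold change 3.87 ± 0.788, or 2.98 without Infertile replicate 2). SAA2, an acute phase protein, was at 3.01 ± 3.65 against 0.171 ± 0.144 CPM. SPTSSB, a subunit of serine palmitoyltransferase, was at 2.67 ± 2.21 against 0.518 ± 0.211 CPM, and PLA2G2F, a secreted phospholipase, at 6.63 ± 4.07 against 0.313 ± 0.363 CPM. SLC6A19, a neutral amino acid transporter, was at 1.52 ± 0.775 against 0.530 ± 0.116 CPM, and AKAP3 was the 1 of the 20 genes with the smallest p that was lower, at 0.106 ± 0.0494 against 0.344 ± 0.148 CPM. Of these 20 genes 11 had classes that did not overlap, which their choice by smallest p favours. Over all genes tested 41, or 0.21%, did not overlap, where chance gives 0.794%. MSMB, a secreted microseminoprotein, had 12 to 23 counts in each Infertile library, 0 in each Sub-fertile library and 0 to 6 in High-fertile libraries. TAP, the tracheal antimicrobial peptide, had 8 to 519 counts in Infertile libraries, 0 in each Sub-fertile library and 0 to 35 in High-fertile libraries.

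All 19 members of the ciliated epithelium list were higher in Infertile than in Sub-fertile heifers, TEKT2, a tektin of the axoneme, at 8.67 ± 3.42 against 4.71 ± 2.61 CPM and TPPP3 at 70.5 ± 23.3 against 52.3 ± 18.9 CPM, a log2 fold change of 0.43 that was 0.25 without Infertile replicate 4 (camera adjusted p = 1.46e-07; adjusted p = 0.900 with an estimated correlation). The ranges of the list mean overlapped (3.55 to 5.00 against 3.03 to 5.07), and the call ended within the 8-library set (median -0.16). The median log2 fold change was 0.49, and between 0.30 and 0.86 with 1 library left out. Interferon-stimulated genes were lower in 36 of 37 cases, OAS1X at 18.5 ± 9.63 against 34.4 ± 15.1 CPM and USP18 at 5.46 ± 1.61 against 8.27 ± 6.15 CPM (camera adjusted p = 0.000493; adjusted p = 0.917 with an estimated correlation). The call ended without Sub-fertile replicate 4, where the median log2 fold change turned from -0.28 to 0.05 and that of USP18 went from -0.60 to -0.01. The proliferation list had 28 of 30 members higher, with a camera adjusted p of 0.000250 and an adjusted p of 0.917 with an estimated correlation. RRM2, a subunit of ribonucleotide reductase, had a log2 fold change of 2.92 ± 0.929 and CCNB2 of 2.51 ± 0.813, or 0.56 and 0.71 without Infertile replicate 2. Its median log2 fold change of 0.89 rested on Infertile replicate 2 and was -0.07 without that library. The macrophage and dendritic cell list had 18 of 19 members higher, VSIG4 at 2.58 ± 1.76 against 1.29 ± 0.166 CPM and LYZ2 at 3.88 ± 2.996 against 1.68 ± 0.775 CPM (camera adjusted p = 0.00271; adjusted p = 0.900 with an estimated correlation). The log2 fold change of VSIG4 went from 1.00 to 0.52 without Infertile replicate 2 and that of LYZ2 from 1.20 to 0.69 without Infertile replicate 1. LYZ2 did not follow its list. It was highest in Infertile replicate 1 (8.57 CPM), where the list mean was the lowest of all libraries. Infertile replicate 2, with the highest list mean (3.21), held 1.83 CPM of LYZ2. How well LYZ2 marks macrophages here was not tested. The call ended without Infertile replicate 2 or Infertile replicate 3 and with the technical set as a covariate (median 0.13). Infertile replicate 2 also held the highest values of CFB (260 CPM), KRT15, S100A8, S100A12 and CXCL5, S100A12 at 28.6 ± 51.6 against 3.99 ± 1.33 CPM. Without that library their log2 fold changes stayed above 0 but went from 3.80 to 0.98 (CFB), 4.68 to 1.86 (KRT15), 2.85 to 0.66 (S100A8), 2.84 to 0.48 (S100A12) and 3.63 to 0.45 (CXCL5). PGR was at 15.7 ± 20.6 against 5.95 ± 4.81 CPM and OXTR at 53.7 ± 73.3 against 7.90 ± 7.57 CPM (edgeR adjusted p = 0.998 for both). These means rested on Infertile replicate 2, at 51.5 and 176 CPM, without which the log2 fold change went from 1.40 to 0.19 for PGR and from 2.76 to 1.55 for OXTR.

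For Infertile against Sub-fertile 0 genes passed the threshold in the edgeR quasi-likelihood test (smallest adjusted p = 0.998), with 525 at an unadjusted p under 0.05 (381 higher, 144 lower) where chance gives 998. The count was 349 with the technical set as a covariate, 314 without Infertile replicate 2 and 1006 without Infertile replicate 5. The edgeR likelihood ratio test passed 18, DESeq2 11, limma-voom with quality weights 0 and without weights 1. The test of any difference among the 3 classes passed 0 genes in edgeR (smallest adjusted p = 0.244; 1681 at an unadjusted p under 0.05, 779 with the technical set as a covariate, 895 without High-fertile replicate 5 and 3072 without Sub-fertile replicate 4), 76 in the likelihood ratio test, 34 in DESeq2, 5331 in limma-voom with quality weights and 1 without weights. Of 84 tests of lists, 17 passed with the preset correlation and 0 with an estimated one. Exact permutation passed 0, but its smallest possible p of 0.00794 came to 0.222 after adjustment. Many lists would have to reach that smallest p for any to pass.

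Log2 fold changes of Sub-fertile and Infertile heifers against the shared High-fertile libraries correlated across the 19962 genes with Pearson r = 0.592, where simulations with no effect gave 0.497 (0.475 to 0.517). Genes are not independent replicates. The covariance was 0.159 against 0.0875 simulated, a difference of 0.0709, and the signs were the same for 79.3% of genes against 66.7% simulated. With the High-fertile libraries divided between the comparisons the mean r over 20 divisions was 0.310 (0.149 to 0.427), against 0.682 with shared libraries on the same scale of mean log2 values. At an unadjusted p under 0.05, 578 genes were higher in both comparisons and 401 lower in both, where simulations with no effect and the shared libraries gave 123 and 82.9 on average and independent lists would share 94 and 55. The simulations leave out the technical sets. Relabelled real libraries reached 578 in 7 of 100 cases, 401 in 9 and the correlation in 36. AZIN1 and HNMT were among the genes higher in both comparisons, and ATP10A and NOTCH4 among those lower in both. None of these 4 passed the threshold over all genes in either comparison (edgeR).

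**Figure D3:**
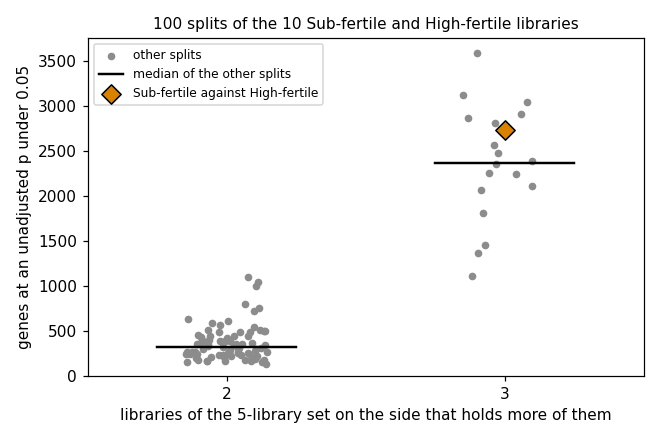
Number of genes at an unadjusted p under 0.05 (vertical axis) in each of 100 splits of the 10 Sub-fertile and High-fertile libraries into 5 against 5, by how many libraries of the 5-library set lay on the side that held more of them (horizontal axis). Grey points are the other splits, bars their medians and the diamond the real classes. The median was 319 with 2 and 2374 with 3 such libraries on a side, and the real classes, with 3, gave 2738.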

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

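Of the tests in this part, those that weigh explanations of Infertile replicate 2 were chosen after the values had been seen, and a library standing far from the others of its class was looked for with Dixon's ratio, which marks about 1 in 20 groups of 5 by chance. It marked 11 of 141 groups, where chance gives 7.

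Sub-fertile replicate 4 had 62.9 M counts against at most 44.2 M in the rest of its class. It also had the highest mean log2 CPM of the interferon-stimulated genes (5.97 against 4.51 to 4.83) and 42.0 CPM of MX2 against 7.05 to 9.45. High-fertile replicate 1 was high on the B and plasma cell list (2.30 against 0.631 to 1.02) and on hypoxia and glycolysis (5.81 against 5.65 to 5.69). High-fertile replicate 4 was low on glucose transporters (2.66 against 3.08 to 3.24) and on integrins and adhesion genes (5.31 against 5.64 to 5.75). High-fertile replicate 5 held 0.264 CPM of LPL, the lipoprotein lipase, against 1.11 to 1.75. Sub-fertile replicate 3 was high on macrophage and dendritic cell genes (2.43 against 2.10 to 2.19).

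Infertile replicate 2 stood above the rest of its class on proliferation (4.37 against 1.76 to 1.98) and on inflammatory cytokines and chemokines (2.61 against 1.51 to 1.77). It held 46.7 CPM of MKI67 and 56.4 CPM of TOP2A, which mark dividing cells, where the other 14 libraries reached 4.17 and 5.70, together with 51.5 CPM of PGR, 176 CPM of OXTR and 0.255 CPM of IGFBP1, a progesterone-induced gene that was at 5.40 to 190 CPM elsewhere. The technical set it shares with High-fertile replicate 1 argues little for its proliferation, since that library was at 2.15, inside the range of the others. Granulocytes alone, on which it was highest (2.15 against at most 1.599 elsewhere), would leave the proliferation list inside that range. Little exposure to progesterone remains a candidate explanation, since its mean of the progesterone-responsive genes, 4.08, was the lowest of 15 (4.38 to 5.36 elsewhere). Members of that list went both ways. SLC5A1 (6.30 CPM) and SERPINA14 (0.085 CPM) were the lowest of 15, and LTF (528 CPM), SPP1 (65.0 CPM) and IGFBP3 (236 CPM) the highest. A library of an animal at another stage of the cycle or a mislabelled one could look the same. Hormone levels are not given in the sources used here.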

How the results depend on the processing

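The settings that use the technical library sets, and limma-voom without weights, were added after the data had been seen; the others were planned. In the edgeR quasi-likelihood test the number of genes past the threshold was 0 in every pairwise comparison and in the joint test under the settings that follow. These were the other scalings, both filters, no robust estimation, 1 surrogate variable and a threshold of 0.10. They also included the technical set as a covariate, only the 8-library set, and leaving out pseudogenes and ribosomal RNA. With only the 10 libraries compared, every pairwise comparison gave 0 and the joint test was not run. Genes past the threshold for Sub-fertile against High-fertile, Infertile against High-fertile, Infertile against Sub-fertile and the joint test were 44, 57, 18 and 76 in the edgeR likelihood ratio test and 19, 34, 11 and 34 in DESeq2. With sample quality weights limma-voom passed 7162, 0, 0 and 5331, with these weights and the technical set 0 in each, and without weights 0, 1, 1 and 1. The 13 libraries outside the 2-library set gave 3 genes for Sub-fertile against High-fertile and 0 otherwise. Leaving out 1 library gave 0 to 3 genes for Sub-fertile against High-fertile (3 without High-fertile replicate 1 or Infertile replicate 5, 1 without High-fertile replicate 3 or Infertile replicate 1) and 0 for the rest. At an unadjusted p under 0.05 these counts for Sub-fertile against High-fertile went from 1120 without Sub-fertile replicate 5 to 4678 without Sub-fertile replicate 4. The cause was not tested except for the technical set.

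The lists past the threshold numbered 17, and 0 with an estimated correlation, 17 to 26 with 1 library left out (26 without Infertile replicate 1), 19 with the technical set and 29 in the 8-library set alone. The correlation of the fold changes, 0.592, was 0.672 over genes above 1 CPM in at least 5 libraries, 0.454 (without Infertile replicate 5) to 0.726 (without Infertile replicate 2) with 1 library left out, 0.678 with the technical set, 0.735 and, with the set, 0.734 over 13 libraries, 0.369 in the 8-library set and 0.310 with divided High-fertile libraries.

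Signs turned for genes that had not passed. For Sub-fertile against High-fertile, the 13 libraries with the technical set gave LMOD1 0.19, SMTN 0.20, MX2 0.35 and PGR 0.17, and the set in all libraries PGR 0.50. MX2 was 0.68 in the 8-library set, limma-voom with weights and the set gave MX2 0.95 and PGR 0.085, and the surrogate variable OXTR 0.071. For Infertile against High-fertile, limma-voom with weights and the set gave ISG15 0.41, MX1 0.039 and MX2 0.47, the 13 libraries with the set MX2 0.17, and limma-voom with weights OXTR -0.13. For Infertile against Sub-fertile, S100A8 was -0.009 in the 8-library set and PGR -0.029 with the surrogate variable and -0.18 over 13 libraries with the set. Among lists, the direction of camera turned for hypoxia (median -0.042 over 13 libraries with the set), for proliferation (-0.075 without Infertile replicate 2, against 1.104 at the most with another library left out, -0.074 over 13 libraries and -0.048 with the set) and for macrophages, Infertile against Sub-fertile (-0.24 in the 8-library set). The median of the interferon-stimulated genes, Infertile against Sub-fertile, turned from -0.28 to 0.05 without Sub-fertile replicate 4, and in the 8-library set those of ciliated epithelium and proliferation turned to -0.16 and -0.008. Of 95 fold changes followed through every setting, no other turned. Depth limits genes such as POU2AF1 and CD79A, with 26 and 45 counts over the 5 Sub-fertile libraries.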

Other observations

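The tests of explanations and the splits of the libraries in this part were chosen after the results had been seen. The smooth muscle list varied most between biopsies, from 4.31 to 8.87 mean log2 CPM, with Infertile replicate 1 the highest (DES, a muscle filament protein, at 2839 CPM). Its 15 members were all lower in Sub-fertile than in High-fertile libraries, and the list did not pass (camera adjusted p = 0.0760; adjusted p = 0.917 with an estimated correlation). Uterine gland genes ranged from 2.06 to 4.35 and epithelium from 4.70 to 6.44. FOXA2, a regulator of gland development, was at 33.2 ± 9.94, 35.8 ± 15.2 and 31.8 ± 5.996 CPM (n = 5 each) in High-fertile, Sub-fertile and Infertile heifers. ISG15 lay between 4.13 and 97.0 CPM in High-fertile, 4.88 and 93.2 CPM in Sub-fertile and 5.58 and 24.8 CPM in Infertile libraries, and the reads of IFNT2, an interferon tau gene of the embryo, came to 0.251 to 1.51 CPM.

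PTGS2, the inducible prostaglandin synthase, was at 57.1 ± 42.5, 57.9 ± 24.4 and 48.9 ± 43.3 CPM, and IGFBP1 at 89.9 ± 30.0, 103 ± 56.3 and 71.8 ± 85.3 CPM. The lists of steroid and oxytocin receptors, prostaglandin synthesis, glucose transporters, WNT signalling, integrins, inflammatory cytokines, antigen presentation, lipid metabolism, epithelium, uterine gland, stromal fibroblast, granulocytes and erythroid cells passed in no comparison without a covariate. With the smooth muscle, T and NK cell, amino acid transporter, heat shock and progesterone-responsive lists, 18 lists did not pass, at camera adjusted p from 0.0514 to 0.994. With the technical set as a covariate, Infertile against High-fertile, epithelium (higher) and stromal fibroblast (lower) passed at a camera adjusted p of 0.0306, at p = 0.426 and p = 0.409 with an estimated correlation. Proliferation (higher) also passed there (camera adjusted p = 0.0431; p = 0.5002 with an estimated correlation), although all Infertile libraries but replicate 2 were at 1.76 to 1.98, below the High-fertile mean of 2.13. The insulin-like growth factor list (lower) passed for Infertile against Sub-fertile (camera adjusted p = 0.0306, and unadjusted p = 0.0136 with an estimated correlation). Every p given for camera with both an estimated correlation and this covariate is unadjusted, so none of them counts as a call. WNT signalling had 24 of 32 members lower in Sub-fertile than in High-fertile libraries, with means of 4.52 ± 0.0940 and 4.79 ± 0.109 that did not overlap (exact permutation p = 0.00794, 0.222 adjusted; camera adjusted p = 0.158). BOLA-DQA1, 1 of several near-identical genes and variable in copy number between animals, was at 5.21 ± 7.22 and 4.82 ± 3.87 CPM in Sub-fertile and Infertile against 0.145 ± 0.0819 CPM in High-fertile heifers.

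The excess of small p values for Sub-fertile against High-fertile, 2738 genes where chance gives 998, may come from the technical library set. With the set as a covariate 501 genes were at an unadjusted p under 0.05, 320 of them among the 2738, and among other splits of the 10 libraries those with all 3 of the 5-library set on 1 side had a median of 2374 genes against 319 for the rest. Within the 8-library set 1528 of 20577 genes tested were at an unadjusted p under 0.05. Of these, 424 were among the 2738, 422 in the same direction, where independent lists would share 205. The overlap is not independent, since the same libraries are in both comparisons. The cause of the 1528 was not tested. Class and set effects are hard to separate for most of these genes, since 64.9% of the 2738 also separate the sets. No High-fertile library lies in the 5-library set. Only the 8-library set holds both classes, with 4 High-fertile and 2 Sub-fertile libraries, which is too few to settle the question.

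For the lower B and plasma cell list in Sub-fertile libraries, the difference within the 8-library set was -1.21 with separate ranges, and -1.25 over all libraries. This argues against the technical set as its whole cause. It rests on 2 Sub-fertile and 4 High-fertile libraries, whose ranges could also separate by chance. Blood in the biopsies could raise HBB with it and stays open. The mean HBB in High-fertile was 1.25 times that in Sub-fertile libraries, 0.935 times without High-fertile replicate 4 and 2.02 times without Sub-fertile replicate 1. HBB had only 14 to 86 counts in these libraries, and how well it marks blood here was not tested, so this ratio cannot decide. The erythroid cell list ran the other way, with 6 of 7 members higher in Sub-fertile libraries, and did not pass (difference 0.253; camera adjusted p = 0.445). Fewer leukocytes of every type could also contribute: the T and NK cell list differed by -0.182, and its shortfall from 0.5 of the B cell difference, 0.441 with a standard error of 0.223, stayed within 2 standard errors. That list also passed as lower with the technical set as a covariate (camera adjusted p = 0.000631), but not with an estimated correlation (unadjusted p = 0.176). Its 2 Sub-fertile libraries in the 8-library set lay on both sides of the High-fertile range (0.544 and 1.62 against 1.17 to 1.54). A lower content of antibody-producing cells in Sub-fertile endometrium is a hypothesis that these data leave open, untested in other heifers.

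Chance could not be excluded for the number of genes at an unadjusted p under 0.05 in any comparison when libraries were regrouped at random. For Sub-fertile against High-fertile, 7 of 100 splits, the real one included, gave at least 2738 genes at an unadjusted p under 0.05 (highest other 3591), for Infertile against High-fertile 13 of 100 gave at least 2201 (3700), for Infertile against Sub-fertile 89 of 100 at least 525 (8245) and for the joint test 15 of 100 at least 1681 (5928). For the count of 0 past the threshold the splits test nothing, since all 100 of 100 give at least 0 by construction, with highest other counts of 1, 0, 6339 and 555. The split of the 10 Infertile and Sub-fertile libraries that followed the 5-library set exactly gave the 6339 genes, which points to a structure of the libraries. With quality weights in limma-voom, 5 of 100 splits gave at least 7162 genes (highest other 7642), all of the 18 others with 3 libraries of the 5-library set on 1 side gave a call, and the count with the set as a covariate was 0. At least 17 lists passed in 80 of 100 relabellings, the real one included (highest other 37, median 22), so the number of lists passed with the preset correlation carries no evidence beyond chance. The correlation of 0.592 was reached in 36 of 100 relabellings (highest other 0.801), the 578 genes higher in both comparisons in 7 of 100 (highest other 1890) and the 401 lower in both in 9 of 100 (highest other 980).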
